A study of Arabidopsis thaliana with 24 samples.

How the data were processed

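Gene expression was measured in leaves of WT and acx1-2 (ACX) Arabidopsis plants with 24 Affymetrix ATH1 arrays, a 1-colour oligonucleotide platform in which several probes per transcript form a probe set. Per the labels' protocols, plants were sprayed with 23 mM 2,4-D in 1% dimethyl sulfoxide and 1% ethanol or with these solvents alone, and total RNA was treated with DNase and cleaned on columns before labelling with biotin. Groups were taken from the labels: WT and ACX at 0 h (6 arrays each), 1 h (3 each) and 72 h (3 each). Per the labels, replicates are independent pools of leaves from at least 5 plants. The deposited values are log2 expression values per probe set that the authors made with RMA, per the submitters' processing notes, which also name limma. RMA as usually run corrects background, quantile-normalizes and summarises the probes of a set. Versions and settings of both tools, and whether all arrays were normalized together, are not given in the sources used here. Quantile normalization gives arrays nearly the same distribution, so a change shared by most genes would be hidden, and RMA compresses changes at the low end. The number of arrays limits the precision. Array images and probe intensities were not used here.

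The table holds 22810 probe sets, of which 64 Affymetrix controls were left out and 22746 tested. Gene names came from the platform annotation of 2016: 13513 tested probe sets have 1 gene, 503 several and 8730 are not listed and are unnamed here. A symbol other than the locus code was given for 1580. No genome coordinates were used. Where a gene of a list had several probe sets, the one with the highest mean over all arrays stood for it.

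The log2 values were used as deposited, with no further scaling and no filter on low values. limma 3.58.1 in R 4.3.3 fitted one mean per group to all 24 arrays (18 residual degrees of freedom, 3.23 prior) with empirical Bayes moderation. The 11 comparisons were each treated group with 0 h in its genotype, ACX with WT at each time, the genotype difference of the change at 1 h and at 72 h, and 72 h with 1 h in each genotype. Benjamini-Hochberg adjustment was made within each comparison over all tested probe sets, with a threshold of 0.05, and probe sets changing at least 2-fold were counted beside it. All p-values are two-sided. Errors of log2 changes are standard errors from this fit, and errors of group means are SDs between arrays.

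The gene lists, the rule for named genes, the tests and the alternatives were chosen before the data were examined, except where stated. There were 33 lists of hormone, oxidative, peroxisomal, detoxification, photosynthetic, wall, cytoskeletal, stress and cell type genes. Of these, 6 had at least 5 named members and were tested with camera (preset correlation 0.01, with an estimated correlation beside it, adjusted over the lists of a comparison): early auxin response, detoxification, photosynthesis, reactive oxygen response, cell wall remodelling, and actin and tubulin. A further 18 had 1 to 4 named members and were reported by member only, and 9 had none. Gene families (30 tested) were written after the annotation was seen and before any comparison. The rule for named genes took ACX1, which the annotation used here does not name, and the 8 largest increases and 8 largest decreases among called genes with a symbol and non-overlapping groups in each treatment comparison, 6 each way for genotype comparisons, the same for differences of the change without the non-overlap condition, and up to 4 members of each list with the smallest adjusted p. A subset of these is named. A gene may be named in a comparison for which another comparison or list selected it.

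Alternatives were centring each array on its median, quantile normalization, filters on the lowest 25% and 50% of probe sets by mean, a 2-fold minimum, a trended and robust prior, array weights, fitting only the groups compared, the replicate number as a block, subsets of the 0 h arrays, 1 probe set per gene and leaving out each array in turn. Fits without ACX 0 h replicates 3 and 6, the crossing of 0 h replicates between genotypes and the divisions of the 0 h arrays were chosen after seeing the data. The replicate numbers are not said to mark a shared batch. The labels give no batch, and scan dates were not used here. The procedure was tested on simulated data drawn from the spread of the real probe sets: for WT at 1 h against 0 h it recovered 92.5% of 2-fold and 98.5% of 4-fold changes, for ACX against WT at 1 h 85.1% and 93.9%, and for the genotype difference of the 72 h change 64.2% and 93.9%, over 22746 probe sets. Camera called 50 of 50 simulated lists shifted by 1 on the log2 scale and 2 of 50 unchanged lists. The simulated probe sets were drawn independently, so these tests do not cover correlation between genes or structure among the arrays.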

Results

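Transcript levels were measured in leaves of Arabidopsis thaliana plants sprayed with 23 mM of the auxinic herbicide 2,4-D. The plants were the wild type (WT, accession Col-0) and the line acx1-2 (called ACX here), which carries an insertion in a gene for acyl-CoA oxidase, the enzyme that opens peroxisomal beta-oxidation. There were 24 Affymetrix ATH1 arrays in 6 groups, with 6 arrays at 0 h, 3 at 1 h and 3 at 72 h for each genotype. Per the labels, each replicate pooled leaves of at least 5 plants, and control plants were sprayed with the solvents alone and sampled at 1 and 72 h. The 6 arrays named 0 h in each genotype are the reference for both times here. Whether they are these solvent controls, and at which time each was sampled, is not given in the sources used here. Changes against 0 h are therefore not separated from effects of the solvents, the spraying, the time of day or leaf age. The deposited log2 values had medians between 5.95 and 6.17 on all arrays. The number of arrays limits the precision, and a typical standard error of a log2 change was 0.128 for a treated group against 0 h.

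Arrays of 1 group correlated at r between 0.974 and 0.997 across probe sets. The first principal component held 58.8% of the variance and placed the 72 h arrays at 87.3 to 111, the 1 h arrays at -22.1 to 2.68 and the 0 h arrays at -49.9 to -32.6. A probe set with no gene name here read 9.45 to 11.6 in the 12 WT arrays and 5.40 to 6.56 in the 12 ACX arrays. It was chosen after its values were seen and is 1 of 3 probe sets that separated all arrays by genotype. The level of the disrupted ACX1 gene itself was not analysed here, since the annotation used names no probe set for it.

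**Figure D1:**
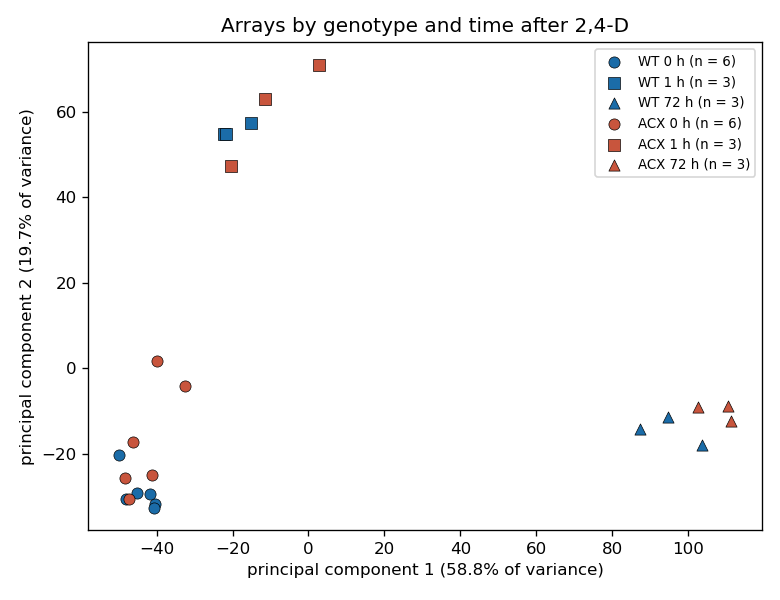
The 24 arrays are plotted by their scores on the first and second principal components of the log2 values, which hold 58.8% and 19.7% of the variance. Each point is an array, coloured and shaped by its group, and the 72 h arrays of both genotypes lie at 87.3 to 111 on the first axis, apart from all others.

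The comparison at 1 h in WT concerns leaves 1 h after spraying with the herbicide. GH3.3, which encodes an enzyme that conjugates auxin to amino acids, went from 4.96 ± 0.12 (SD, n = 6) to 13.36 ± 0.16 (SD, n = 3) on the log2 scale, a 340-fold increase (log2 change 8.41, SE 0.30, adjusted p = 1.77e-14). The glycosyltransferase genes UGT73B5 (log2 change 5.82), UGT73C1 (5.25), UGT76B1 (3.98) and UGT73B4 (3.84) rose as well, together with SUFE2 (4.66), the Aux/IAA gene IAA29 (4.36) and the transporter gene OCT5 (4.29). Genes that fell included the transcription factor gene ORA47 (-3.31, SE 0.42, adjusted p = 3.62e-06), the cold-regulated gene COR15A (-2.75), the pectin methylesterase gene ATPMEPCRB (-2.35) and WRKY53 (-2.05, adjusted p = 0.000433). GH9C2 (-1.89), MSRB5 (-1.86), which encodes a methionine sulfoxide reductase, and XTH32 (-1.81), which encodes a xyloglucan-modifying enzyme, also fell. Of 10 measured members of the early auxin response list, 6 rose and none fell (7 rose when adjusted over the list alone), among them WES1 (3.25) and IAA30 (2.68), and the list was higher than other genes by camera (adjusted p = 6.66e-08; adjusted p = 0.000711 with an estimated correlation). Of 5 measured detoxification genes, 4 rose, including GSTU25 (3.35) and IAGLU (2.60), with adjusted p = 1.25e-06 by camera and adjusted p = 0.00268 with an estimated correlation. Of the 10 photosynthesis genes, 0 passed the test (camera adjusted p = 0.66). Of 6 genes responsive to reactive oxygen, 2 rose, AT2G21640 (4.58-fold) and NDB2 (log2 change 1.92), and 1 fell, WRKY53; the list's median (-0.63) and mean (-0.01) were negative while camera pointed up (adjusted p = 0.991). Both heat shock genes measured rose, AT2G29500 by 4.25 and ATHSP22.0 by 1.21, as did BZIP60 (1.18) and ATERDJ3B (0.78) of endoplasmic reticulum folding. Both measured response regulator genes of the cytokinin list fell, ARR15 (-1.30) and RR16 (-1.23), and the clock gene GI fell by 1.52. BIGYIN, whose product acts in the division of peroxisomes, rose by 1.07. In all, 6068 of 22746 probe sets changed (2509 higher, 3559 lower), of which 1624 changed at least 2-fold (835 higher, 789 lower). With array centring 2901 were higher and 2910 lower. Among 8 cell wall remodelling genes 1 rose and 1 fell (camera adjusted p = 0.991), and of 9 actin and tubulin genes 2 rose and 2 fell (adjusted p = 0.991).

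In ACX at 1 h GH3.3 rose by 7.78 (SE 0.30, adjusted p = 5.08e-14), UGT73C1 by 5.28, UGT73B5 by 4.94, OCT5 by 4.56, IAA29 by 4.41, SUFE2 by 3.80, UGT73B4 by 3.58 (4.25 without ACX 1 h replicate 1) and AER, which encodes an alkenal reductase, by 3.55. ATPMEPCRB (-3.14), ORA47 (-3.14), GTR1 (-2.71), XTH18 (-2.52), the expansin-like gene EXLA1 (-2.52), WRKY53 (-2.49), MSRB5 (-2.46) and the ubiquitin ligase gene PUB23 (-2.40, adjusted p = 9.67e-07) fell. In the early auxin list 6 of 10 members rose (6 when adjusted over the list alone), including IAA30 (3.31) and WES1 (2.75), with camera adjusted p = 3.99e-07 and adjusted p = 0.00128 with an estimated correlation. Of 5 detoxification genes 4 rose, among them GSTU25 (10.6-fold) and IAGLU (log2 change 3.24), with adjusted p = 2.68e-06 and, with an estimated correlation, adjusted p = 0.00347. The size of the GSTU25 change rests on single arrays: its log2 change was 4.26 without ACX 1 h replicate 1 and 2.63 without ACX 1 h replicate 3. At 0 h GSTU25 read 4.04 in WT and 4.06 in ACX, below the lower quartile of each 0 h array (4.48 to 4.61). RMA compresses changes at this low end. Of 6 genes responsive to reactive oxygen 2 rose and 4 fell, the latter including STZ (-1.81) and CML38 (-2.06), and camera did not place the list below other genes (adjusted p = 0.224). The heat shock gene AT2G29500 rose by 3.55. Of 10 photosynthesis genes 2 fell (list adjusted p = 0.173), of 8 wall remodelling genes 1 rose and 1 fell (adjusted p = 0.306), and of 9 actin and tubulin genes 2 rose and 3 fell (adjusted p = 0.561). Of 22746 probe sets 5367 changed (2469 higher, 2898 lower), 1628 of them at least 2-fold; array centring gave 2705 higher and 2597 lower. Leaving out ACX 1 h replicate 3 lowered the count to 3478. WT and ACX share no arrays in these comparisons: 1817 probe sets rose and 2114 fell in both, against 272 and 453 for independent lists, while 7 and 5 went in opposite directions, and the changes correlated across probe sets at r = 0.863 (probe sets are not independent replicates).

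**Figure D2:**
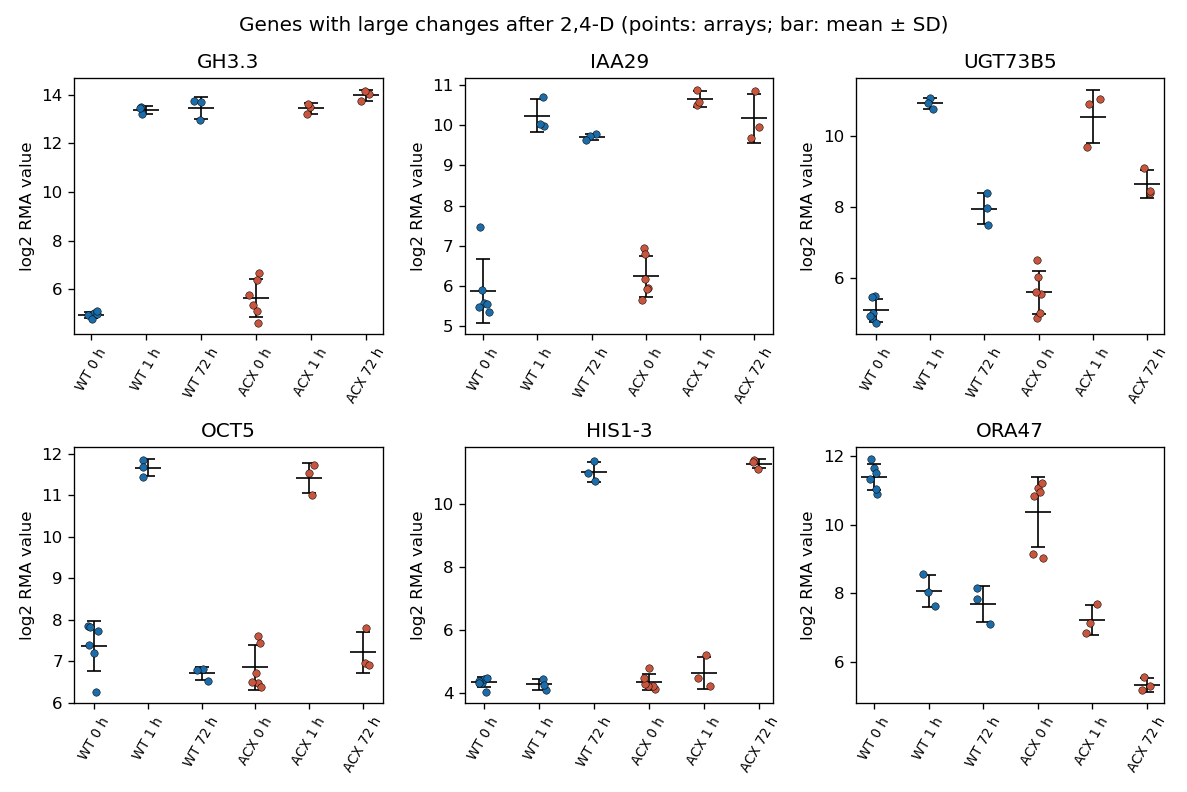
Log2 expression of GH3.3, IAA29, UGT73B5, OCT5, HIS1-3 and ORA47 is plotted for each array by genotype and time (0, 1 and 72 h), with the group mean and SD as bar and whisker. GH3.3 lies near 13.4 in both treated WT groups against 4.96 at 0 h, and HIS1-3 in WT lies at 4.33 at 0 h and 11.01 at 72 h.

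At 72 h in WT the comparison concerns leaves 72 h after spraying. The linker histone gene HIS1-3 rose from 4.33 ± 0.16 (SD, n = 6) to 11.01 ± 0.32 (SD, n = 3), a log2 change of 6.68 (SE 0.18, adjusted p = 3.15e-17). Its 0 h mean lay below the lower quartile of each WT 0 h array (4.50 to 4.61), where RMA compresses changes. GH3.3 (8.50), the transcription factor gene UPB1 (6.20), WES1 (5.20), the late embryogenesis gene LEA4-5 (5.04) and the calmodulin-like gene CML41 (4.98) rose. Genes that fell included TBL26 (-4.54), MSRB6 (-4.00), STOMAGEN (-3.71), whose peptide promotes stomatal development, ORA47 (-3.69), the protochlorophyllide reductase gene PORB (-3.56), the thionin gene THI2.2 (10.6-fold lower), CSLA03 (-3.33) and the actin gene ACT11 (-3.31, SE 0.16, adjusted p = 1.08e-13). Of 10 photosynthesis genes 9 fell and none rose, including SBPASE (-1.28) and PSBY (-1.03), with camera adjusted p = 2.58e-05 and adjusted p = 0.0498 with an estimated correlation. The chlorophyll gene CHLM fell by 2.14. Of the 9 actin and tubulin genes 7 fell, ACT11 and TUB5 (-2.12) among them; camera gave adjusted p = 0.00164, and with an estimated correlation the call was lost (adjusted p = 0.0648). In the early auxin list 9 of 10 members rose and 1 fell, with GH3.1 at 3.06 (adjusted p = 4.63e-06; adjusted p = 0.00304 with an estimated correlation). Of 5 detoxification genes 3 rose and the list was not called (adjusted p = 0.109), and of 8 wall remodelling genes 2 rose, XTH20 (1.80; 2.50 without WT 72 h replicate 1) and EXPA4 (2.40), and 5 fell, XTH18 (-2.24) among them (list adjusted p = 0.602). Of 6 reactive oxygen genes 3 fell, CML38 (-2.65), STZ (-1.98) and WRKY53 (-1.45) (list adjusted p = 0.109). Among peroxisomal genes AIM1 of beta-oxidation rose by 1.63 and BIGYIN by 0.80; the thylakoid peroxidase gene TAPX fell by 2.23 while the glutathione reductase gene GR1 rose by 0.82. The jasmonate genes OPCL1 (-1.60) and PDF1.2 (-2.81) and the response regulator ARR15 (-2.68) fell, and the sugar transporter gene SAG29 rose by 2.84 (3.62 without WT 72 h replicate 1 and 2.18 without replicate 3). Of the guard cell markers, AT1G22690 fell by 3.58 (4.22 without WT 72 h replicate 1) and FMA had a change of -0.40 (adjusted p = 0.0187). The FMA call was lost without WT 72 h replicate 3 (-0.14, adjusted p = 0.329), with 0 h replicates 1 to 3 only (-0.30, 0.137) and when only the groups compared were fitted (0.0889). In all 12153 probe sets changed (6007 higher, 6146 lower), 4396 of them at least 2-fold. Centring each array on its median moved the median change of all probe sets from -0.06 to -0.21 and gave 4948 higher and 10521 lower; changes are relative to the deposited scale. The log2 changes at 1 h and 72 h correlated at r = 0.383 (covariance 0.219), but both use the same 0 h arrays. Unchanged simulated groups gave r = 0.332 (covariance 0.00992), and with the 0 h arrays divided r was 0.381. At both times 1460 probe sets were higher and 1861 lower than at 0 h, 227 were higher at 1 h and lower at 72 h, and 665 the reverse. Independent lists would give 663, 962, 678 and 940, a reference that leaves out the shared 0 h arrays.

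In ACX at 72 h GH3.3 rose by 8.31 (SE 0.30, adjusted p = 1.79e-15), LEA4-5 by 7.11 and HIS1-3 by 6.93. UPB1 (5.89), the dehydrin gene LTI30 (5.40), the anthocyanin pathway gene DFR (5.39), which encodes dihydroflavonol reductase, the aldehyde dehydrogenase gene ALDH7B4 (4.87) and SAG29 (4.77) rose as well. ORA47 (-5.02), MSRB6 (-4.94), THI2.2 (-4.71), STOMAGEN (-4.69), EXO (-4.28), XTH18 (-4.23), TBL26 (-4.18) and ACT11 (-3.43, adjusted p = 4.81e-14) were among the genes that fell. EXO varied widely among the ACX 0 h arrays (SD 1.47, n = 6). Both measured flavonoid genes rose, the second being UF3GT (3.39), which encodes an anthocyanin glycosyltransferase. Of 10 photosynthesis genes 9 fell, among them SBPASE (-1.67) and PSBY (-1.40), with camera adjusted p = 2.89e-06 and adjusted p = 0.0282 with an estimated correlation. In the early auxin list 9 of 10 rose and 1 fell, with WES1 at 4.05 and GH3.1 at 3.72 (adjusted p = 1.15e-06; adjusted p = 0.00184 with an estimated correlation). Of 5 detoxification genes 4 rose, including UGT73B5 (3.05) and UGT73B4 (1.89); adjusted p was 0.0492 by camera and adjusted p = 0.189 with an estimated correlation. GSTU25, of the same list, rose by 1.64, but without ACX 72 h replicate 1 its change was 0.89 (adjusted p = 0.121). Of 6 reactive oxygen genes 4 fell and 1 rose, with CML38 at -3.64 and STZ at -3.57; the list passed with adjusted p = 0.0492 and not with an estimated correlation (adjusted p = 0.286). Both list calls were also lost with 0 h replicates 1 to 3 only or 4 to 6 only (adjusted p 0.0650 to 0.104), the reactive oxygen list with array centring (adjusted p = 0.1) and the detoxification list with quantile normalization (adjusted p = 0.0526). Of 9 actin and tubulin genes 5 fell (adjusted p = 0.00892; adjusted p = 0.129 with an estimated correlation), and of 8 wall remodelling genes 2 rose, XTH20 (2.79) and EXPA4 (2.72), and 4 fell (list adjusted p = 0.426). Of the guard cell markers, AT1G22690 fell by 5.54 and FMA by 0.88 (adjusted p = 2.5e-12 and 1.16e-05). Such falls were not particular to guard cell markers. The trichome gene TRY had means of 7.41 at 0 h and 4.86 at 72 h in ACX, and 8.08 and 5.23 in WT. In all 12115 probe sets changed (5980 higher, 6135 lower), 4518 at least 2-fold; array centring gave 5007 higher and 10012 lower. Across genotypes 4842 probe sets rose in both and 4550 fell in both, against 1580 and 1660 for independent lists, and the changes correlated at r = 0.899. Within ACX, the 1 h and 72 h changes, which share the 0 h arrays, correlated at r = 0.447 (covariance 0.27), against r = 0.336 (covariance 0.01) for unchanged simulated groups and r = 0.373 with the 0 h arrays divided.

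**Figure D3:**
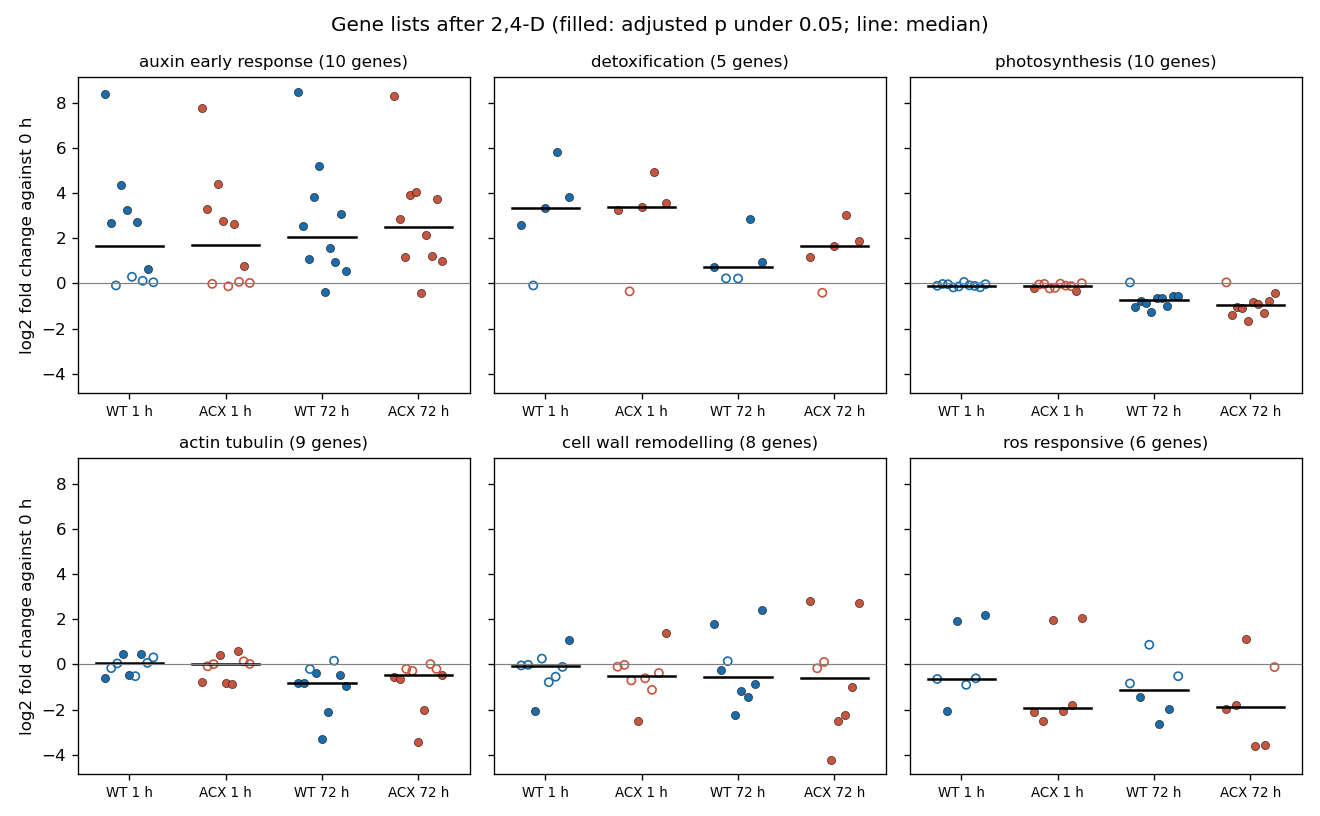
Log2 change against 0 h (vertical axis) of each measured gene of the 6 tested lists in the 4 treatment comparisons, blue for WT and red for ACX. Each point is a gene, filled where its adjusted p is under 0.05, and the black line is the list's median. The early auxin list lies at 1.65 (WT) and 1.70 (ACX) at 1 h, and photosynthesis at -0.72 (WT) and -0.98 (ACX) at 72 h.

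At 0 h the comparison asks how ACX differs from WT without the herbicide. COR15A was lower in ACX by 2.27 (SE 0.29, adjusted p = 9.85e-05), from 9.75 ± 0.49 (SD, n = 6) to 7.48 ± 0.23 (SD, n = 6), and so were the related COR15B (-1.45), the clock gene GI (-1.46), PORB (-1.15) and SAG29 (-1.18). CML41 (2.40), XTH18 (1.96), the starch-related gene QQS (1.51) and WES1 (1.27) were higher. Without ACX 0 h replicates 5 or 6, or WT 0 h replicates 4 or 6, SAG29 had differences of -1.12 to -1.15 with adjusted p from 0.0509 to 0.0589. Its call was also lost without ACX replicates 3 and 6 (adjusted p = 0.0806), with replicates 1 to 3 only (-0.76, 0.319) and in both crossings of replicates (0.364 and 0.118). With WT replicates 1 to 3 set against ACX replicates 4 to 6, COR15B (adjusted p = 0.121), PORB (0.0592) and GI (0.0704) lost their calls, GI also with replicates 1 to 3 only (0.068) and PORB also in the reverse crossing (0.115). Of 6 reactive oxygen genes 1 was higher, STZ (0.86, not called in any fit with 3 of the 0 h arrays per genotype, adjusted p 0.0608 to 0.214), with camera adjusted p = 0.0395 for the list and adjusted p = 0.252 with an estimated correlation. The list's call was lost with replicates 1 to 3 only (median 0.69, adjusted p = 0.0808) and with 4 to 6 only (median 0.14, adjusted p = 0.597). In all 1671 probe sets differed (787 higher in ACX, 884 lower), 243 of them at least 2-fold; array centring gave 886 higher and 821 lower. The 0 h arrays are not uniform: without WT 0 h replicate 1 the count was 1085, with replicates 1 to 3 only it was 2691, with replicates 4 to 6 only 4184, and crosswise (WT 1 to 3 with ACX 4 to 6, and the reverse, chosen after seeing the data) 493 and 924. In WT, replicates 1 to 3 differed from 4 to 6 at 1294 probe sets and the other 9 divisions at 0; in ACX the same division gave 176, replicates 1, 2 and 4 against the rest 244, replicates 1, 4 and 5 against the rest 498, and the other 7 divisions 0. Without ACX 0 h replicates 3 and 6, also left out only after seeing the data, 1101 probe sets differed.

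At 1 h after spraying, 8 probe sets differed between the genotypes at adjusted p under 0.05 (5 higher in ACX, 3 lower) and 1041 at an unadjusted p under 0.05. QQS was higher in ACX by 1.86 (SE 0.24, adjusted p = 0.000768), 10.10 ± 0.19 against 8.24 ± 0.06 (SD, n = 3 each). CCL was higher by 1.49 (adjusted p = 0.0337) and IVD, which encodes isovaleryl-CoA dehydrogenase, by 1.08 (adjusted p = 0.0473). Both lost the call without ACX 1 h replicate 1 or 3 or WT 1 h replicate 1 or 2, with CCL at 1.28 to 1.48 (adjusted p 0.0671 to 0.472) and IVD at 0.85 to 1.09 (adjusted p 0.109 to 0.668). Both also lost it when only the 6 arrays at 1 h were fitted (adjusted p = 0.603 and 0.605), and IVD with array weights (0.75, adjusted p = 0.0593) and with 1 probe set per gene (adjusted p = 0.0529). The count was 4 without ACX 1 h replicate 3, WT 1 h replicate 1 or WT 1 h replicate 2, 13 without ACX 1 h replicate 1, 14 without ACX 1 h replicate 2, 4 when only the 6 arrays at 1 h were fitted, 45 with array weights and 3 with 1 probe set per gene. No list other than actin and tubulin was called (adjusted p = 0.0295; adjusted p = 0.402 with an estimated correlation), and 0 of its 9 members passed on its own. The change from 0 to 1 h differed between genotypes at 33 probe sets (12 higher, 21 lower). The size by which the ACX change exceeded the WT change was 2.74 (SE 0.51, adjusted p = 0.0286) for COR15A and 1.70 for EXPA16; it was -2.77 (adjusted p = 0.00676) for XTH18, -1.42 for GTR1 and -1.15 for the ATP sulfurylase gene APS3. This count was 1122 with 0 h replicates 4 to 6 only, 17 with 1 to 3 only, 322 with array weights, 70 without ACX 0 h replicates 3 and 6 and 18 with 1 probe set per gene. Left-out arrays moved it between 6 (without ACX 1 h replicate 1) and 138 (without WT 0 h replicate 3). It was also 9 without WT 1 h replicate 1 or 2, 15 without WT 0 h replicate 4 or 6, 19 without ACX 0 h replicate 5 and 21 without WT 0 h replicate 1. GTR1, COR15A and EXPA16 each lost the call without ACX 1 h replicate 1, WT 1 h replicate 1 or WT 1 h replicate 2 (adjusted p up to 0.0741, 0.112 and 0.106). COR15A and EXPA16 also lost it without ACX 1 h replicate 2, WT 1 h replicate 3 or WT 0 h replicates 4 or 6, and EXPA16 without ACX 1 h replicate 3, ACX 0 h replicates 1 or 5 or WT 0 h replicate 2, at changes of 2.58 to 2.87 for COR15A, 1.62 to 1.79 for EXPA16 and -1.36 to -1.23 for GTR1. With 0 h replicates 1 to 3 only, the calls of XTH18 (-2.59, adjusted p = 0.0595), COR15A (2.26, 0.145) and EXPA16 (1.71, 0.0859) were lost. The list of reactive oxygen genes had adjusted p = 0.00688 for the difference of the change (median -0.80) and adjusted p = 0.425 with an estimated correlation, and with 0 h replicates 4 to 6 only adjusted p was 0.529.

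**Figure D4:**
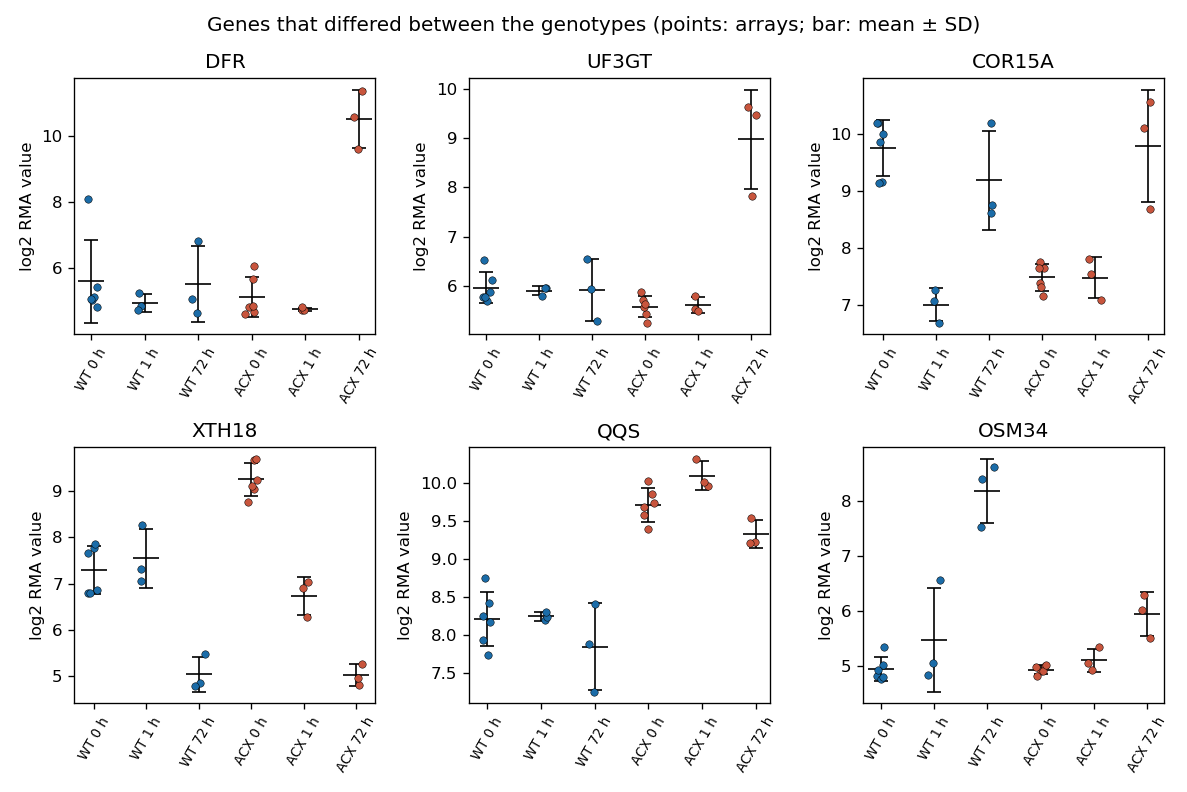
Log2 expression of DFR, UF3GT, COR15A, XTH18, QQS and OSM34 is plotted for each array (point) by genotype and time, with the group mean and SD as bar and whisker. DFR stands at 10.5 in ACX at 72 h and at 5.53 in WT, and COR15A at 0 h stands at 9.75 in WT and 7.48 in ACX.

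At 72 h, DFR was higher in ACX by 4.99 (SE 0.66, adjusted p = 0.000193), 10.51 ± 0.87 against 5.53 ± 1.16 (SD, n = 3 each). Without WT 72 h replicate 3 the difference was 5.64. UF3GT (3.05, adjusted p = 1.96e-05), APL4 (1.92), which encodes an ADP-glucose pyrophosphorylase subunit, the sugar transporter gene SWEET4 (1.66) and LEA4-5 (1.65) were higher, and ORA47 (-2.36), the osmotin gene OSM34 (-2.24), the transcription factor gene HYH (-1.14) and the MADS-box gene AGL42 (-1.02) were lower. In all 635 probe sets differed (355 higher, 280 lower), 209 at least 2-fold; array centring gave 388 higher and 210 lower. Camera placed the early auxin list above other genes in ACX (median difference 0.43, adjusted p = 0.00198; adjusted p = 0.0395 with an estimated correlation), with 1 of 10 members called and 3 when adjusted over the list alone. Of 10 photosynthesis genes 1 was lower, SBPASE (-0.37), and 9 did not pass the test. Camera placed the list below other genes (median -0.18, adjusted p = 0.00208), but not with an estimated correlation (adjusted p = 0.178). SBPASE lost its call without ACX 72 h replicate 1 or 3 or WT 72 h replicate 1 or 2 (adjusted p up to 0.205) with array centring (adjusted p = 0.0909) and without the lower 50% of probe sets by mean (0.0512). SWEET4 lost it without the same arrays (adjusted p up to 0.14), HYH without ACX 72 h replicate 2 or 3 or WT 72 h replicate 1 or 2 (up to 0.236) and with 1 probe set per gene (0.0549), LEA4-5 without ACX 72 h replicate 3 or WT 72 h replicate 1 or 2 (up to 0.122) and ORA47 without WT 72 h replicate 2 (0.0509). Fitting only the 6 arrays at 72 h left 2 probe sets, and none of these 10 genes kept its call (DFR adjusted p = 0.0617, UF3GT 0.0775). Without ACX 72 h replicate 3 the count was 262, without WT 72 h replicate 1 it was 209 and without WT 72 h replicate 2 it was 334, while array weights gave 1357. The change from 0 to 72 h differed between genotypes at 1362 probe sets (705 higher, 657 lower), and at 747, 705 and 848 without the same 3 arrays. It was 2914 with 0 h replicates 4 to 6 only and 2444 with array weights. Of the 657 lower, 337 were called higher in ACX at 0 h, and of the 705 higher, 293 were called lower at 0 h, while 191 and 276 were called in the same direction at 72 h. The test shares its arrays with both of these comparisons. CML41 and XTH18, higher in ACX at 0 h, had differences of 0.14 and -0.03 at 72 h. DFR (5.47, SE 0.81, adjusted p = 0.000575), UF3GT (3.43), COR15A (2.87) and LEA4-5 (2.07) had more positive changes in ACX than in WT, and MSRB9 (-2.30), CML41 (-2.26), OSM34 (-2.24) and XTH18 (-1.99) less positive or more negative ones. CML41 lost this call without ACX 72 h replicate 3 (-2.15, adjusted p = 0.0529) and MSRB9 without 6 arrays (any of the 3 ACX 72 h replicates, WT 72 h replicates 1 or 2 and WT 0 h replicate 4; adjusted p up to 0.115). CML41 also lost it with 0 h replicates 1 to 3 only (adjusted p = 0.0639) and LEA4-5 with replicates 4 to 6 only (1.28, adjusted p = 0.0579), and MSRB9 with either (adjusted p = 0.0793 and 0.0614) and without ACX 0 h replicates 3 and 6 (0.0601). For photosynthesis genes the difference of the change had a median of -0.24 (adjusted p = 0.00726; adjusted p = 0.425 with an estimated correlation), and the call was lost with 0 h replicates 1 to 3 only or 4 to 6 only (adjusted p = 0.105 and 0.136). Of the guard cell markers, AT1G22690 fell further in ACX (-1.97, adjusted p = 0.0118, with -1.33 without WT 72 h replicate 1 and -2.51 without WT 72 h replicate 3). Its call was lost without ACX 72 h replicate 3 (-1.68, adjusted p = 0.0537) and with 0 h replicates 4 to 6 only (-1.72, 0.0627). Part of this difference lies at 0 h, where AT1G22690 read 11.1 in ACX and 10.1 in WT, against 5.5 and 6.5 at 72 h. FMA had a difference of -0.48 (adjusted p = 0.166).

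Between 1 h and 72 h, 9 of 10 photosynthesis genes fell in both genotypes and 1 rose in ACX (medians -0.71 in WT and -0.85 in ACX). Camera called the list (adjusted p = 0.000148 and 1.42e-05) but not with an estimated correlation (adjusted p = 0.0665 and 0.0708). In all 11293 probe sets changed in WT (5736 higher, 5557 lower) and 10509 in ACX (5374 higher, 5135 lower). Array centring gave 4316 higher and 10451 lower in WT and 4199 higher and 9218 lower in ACX, since it moved the median change of all probe sets from -0.04 to -0.25 and from -0.04 to -0.22. Of the 5 detoxification genes, the median change from 1 to 72 h was -2.90 in WT and -1.76 in ACX; 4 of 5 fell in each. Camera called both lists (adjusted p = 0.0160 and 0.0292), but neither with an estimated correlation (adjusted p = 0.104 and 0.125) nor with array centring (adjusted p = 0.0566 and 0.0743).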

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

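In this part, the test of a swapped array and that of 0 h replicates running opposite ways (the crosswise comparison) were chosen only after the result was seen, and the fit without ACX 0 h replicates 3 and 6 was added after seeing the data.

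In 10 gene and group combinations 1 array lay far from the 5 others of its group, out of 166 tested, where chance gives about 1 in 20 or 8.3. All 10 were in WT 0 h and 9 of them in replicate 3: IAA29 read 7.47 there (others 5.34 to 5.89), WRKY53 8.55 (9.50 to 9.91), PDF1.2 5.45 (6.96 to 7.49), NDB2 7.24 (9.09 to 9.51), PORB 10.52 (8.99 to 9.20), BZIP60 9.08 (9.78 to 10.02), DFR 8.11 (4.83 to 5.44), TBL26 8.93 (11.17 to 11.74) and HYH 7.22 (8.34 to 8.94). SWEET4 read 6.32 in WT 0 h replicate 5 (5.47 to 5.78). The number is near what chance gives, while 9 of the 10 lie in 1 array. Without that array the 0 h genotype count was 2263 in place of 1671.

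The change at 1 h differed between the genotypes at 33 probe sets by the test of the difference itself. The named genes among them were COR15A (2.74), EXPA16 (1.70), XTH18 (-2.77), GTR1 (-1.42) and APS3 (-1.15), in the sense of the ACX change minus the WT change. Each of them had a 0 h mean difference between the genotypes of the opposite sign. The difference of the change contains the same 0 h arrays, so for genes picked by its size an opposite sign is partly built in. COR15A was lost without ACX 1 h replicates 1 or 2, WT 1 h replicates 1, 2 or 3 or WT 0 h replicates 4 or 6 (2.58 to 2.87), EXPA16 without any array at 1 h, ACX 0 h replicates 1 or 5 or WT 0 h replicates 2, 4 or 6 (1.62 to 1.79), and GTR1 without ACX 1 h replicate 1 or WT 1 h replicates 1 or 2 (-1.36 to -1.23). Of 100 divisions of the arrays drawn, 3 gave as many as 33, the real one included, with 152 the highest other, a share under 0.05. The draws mixed the genotypes at each time, so the share does not concern the difference of the change alone. A division calling several times the real count points to a structure of the arrays. Chance is therefore not excluded for this count. Without WT 0 h replicate 3 the count was 138, without ACX 1 h replicate 1 it was 6, without WT 1 h replicate 1 or 2 it was 9, without WT 0 h replicate 4 or 6 it was 15, without ACX 0 h replicate 5 it was 19 and without WT 0 h replicate 1 it was 21. With 0 h replicates 4 to 6 only it was 1122, with 1 to 3 only 17 and with array weights 322.

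The change at 72 h differed at 1362 probe sets, 1 of 100 divisions giving as many (highest other 498), a share under 0.05. These draws too mixed the genotypes at each time, so the share does not concern the difference of the change alone. Of the probe sets called, 337 with a negative difference were higher in ACX at 0 h and 293 with a positive one were lower at 0 h, from the same 0 h arrays. The ACX change minus the WT change was positive for DFR (5.47), UF3GT (3.43), COR15A (2.87), LEA4-5 (2.07), APL4 (2.01), SAG29 (1.94), COR15B (1.77), SWEET4 (1.72), RR16 (1.67), GH9C2 (1.47), UGT73C1 (1.41), EXPA16 (1.21), ALDH7B4 (1.09) and AER (0.80). It was negative for MSRB9 (-2.30), CML41 (-2.26), OSM34 (-2.24), XTH18 (-1.99), AT1G22690 (-1.97), STZ (-1.59), APS3 (-1.57), PUB23 (-1.46), THI2.2 (-1.30), AT2G29500 (-1.17), WES1 (-1.16), GTR1 (-1.09), ATERDJ3B (-0.86), AGL42 (-0.84) and SBPASE (-0.39). RR16 fell by 1.58 in WT and had a change of 0.09 in ACX (adjusted p = 0.808). At 0 h RR16 already read 4.90 in ACX against 6.16 in WT. Some of these genes were selected for other comparisons. RR16 and CML41 lost the call without ACX 72 h replicate 3 (1.52 and -2.15, adjusted p = 0.0534 and 0.0529), as did AT1G22690 (-1.68, 0.0537). Without WT 72 h replicate 3, DFR was at 6.13 and SAG29 at 2.59. AT2G29500 lost it without ACX 72 h replicates 2 or 3, WT 72 h replicates 1 or 2, ACX 0 h replicate 5 or WT 0 h replicates 1 or 6 (-1.21 to -0.87, adjusted p up to 0.147). SAG29 lost it without 9 arrays (ACX 72 h 2 and 3, WT 72 h 1 and 2, ACX 0 h 5 and 6, WT 0 h 4, 5 and 6; 1.16 to 2.06, adjusted p up to 0.139), SBPASE without 11 (ACX 72 h 1 and 3, WT 72 h 1 and 2, ACX 0 h 1, 4, 5 and 6, WT 0 h 1, 4 and 6; -0.40 to -0.32, up to 0.148) and MSRB9 without 6 (all ACX 72 h, WT 72 h 1 and 2, WT 0 h 4; -2.37 to -2.04, up to 0.115). With 0 h replicates 1 to 3 only, RR16 (1.1, adjusted p = 0.136), SAG29 (1.51, 0.198), SBPASE (-0.35, 0.151), ATERDJ3B (-0.82, 0.0568), CML41 (-2.31, 0.0639) and MSRB9 (-2.23, 0.0793) lost the call, and with 4 to 6 only LEA4-5 (1.28, 0.0579), MSRB9 (-2.37, 0.0614), AT1G22690 (-1.72, 0.0627) and AT2G29500 (-0.91, 0.143). Without ACX 0 h replicates 3 and 6, SBPASE (-0.40, 0.0568), SAG29 (1.90, 0.0615) and MSRB9 (-2.17, 0.0601) lost it. SBPASE also lost it with array centring (-0.37, 0.0869) and without the lowest 25% or 50% of probe sets by mean (0.0538 and 0.0501), and SAG29 when only the groups compared were fitted (0.0699). Without ACX 72 h replicate 3 and WT 72 h replicates 1 and 2 in turn, the counts were 747, 705 and 848; with 0 h replicates 4 to 6 only the count was 2914 and with array weights 2444.

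Counting the real division itself, as many calls were made in 1 of 84 divisions of the same arrays for WT at 1 h (6068, highest other 2541), WT at 72 h (12153, highest other 4953), ACX at 1 h (5367, highest other 2072) and ACX at 72 h (12115, highest other 2873), and in 1 of 100 for ACX against WT at 0 h (1671, highest other 1450). Each is a share under 0.05. The highest other division set apart WT 0 h replicates 4 to 6 (with WT 1 h), WT 0 h replicates 1 to 3 (with WT 72 h), ACX 0 h replicates 1, 2 and 4 (with ACX 1 h) and ACX 0 h replicates 4 to 6 (with ACX 72 h), a structure among the 0 h arrays. For the remaining comparisons 10 divisions are too few for a share under 0.05: ACX against WT at 1 h gave 8 with 62 the highest other (2 of 10 as large), at 72 h 635 with 45, and 72 h against 1 h gave 11293 with 1 in WT and 10509 with 2 in ACX (1 of 10 each). At 1 h a division mixing the genotypes thus called several times the real number, which points to a structure among these 6 arrays.

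The genotypes differed at 1671 probe sets at 0 h and at 8 at 1 h. With 3 arrays per genotype the lower count at 0 h was 2691, and with WT and ACX replicates crossed it was 493, both well above 8. The crossing counters the opposite course of replicates 1 to 3 and 4 to 6 in the genotypes (r = -0.487 across probe sets). These fits left 0 h arrays out of the shared spread, while the 8 came from the fit to all arrays. They also do not cover the structure at 1 h, where a mixed division called 62. Whether fewer arrays at 1 h account for the gap is thus not decided. A swap of arrays at 1 h is argued against because 6 of 6 arrays lay on their labelled side over 23 probe sets called alike at 0 h and 72 h. ACX 0 h arrays that stand apart may contribute, since without replicates 3 and 6 the count was 1101, just below the bound of the main count divided by 1.5, although leaving out WT 0 h replicate 1 alone gave 1085. The test of the difference between the genotypes in the change from 0 to 1 h called 33 probe sets (6 to 1122 over the alternatives), and the genotype differences at 0 h and 1 h, which share no arrays, correlated across probe sets at r = 0.234 with 58.3% of the same sign, so that whether the genotypes differ less 1 h after spraying stays open.

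DFR and UF3GT were higher in ACX at 72 h. A single array does not account for it, as the highest adjusted p of both over fits leaving out an array was 0.00216, nor does scaling, as the lowest of 4 scaled differences was 3.08. A fit of the 6 arrays at 72 h alone gave adjusted p = 0.0617 and 0.0775 at unchanged differences of 4.99 and 3.05. Fewer arrays then estimate the spread. For UF3GT the SD was also larger at 72 h (0.62 in WT and 1 in ACX) than in the other groups (0.09 to 0.31). The fit to all arrays may thus understate its spread at 72 h. A biological difference of the anthocyanin genes between the treated genotypes is a hypothesis that these tests leave standing.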

How the results depend on the processing

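The crosswise 0 h comparison and the fits without ACX 0 h replicates 3 and 6 were chosen only after seeing the data; the other settings were planned. Order below: WT 1 h, WT 72 h, ACX 1 h, ACX 72 h (each against 0 h), ACX against WT at 0 h, 1 h and 72 h, difference of the 1 h and 72 h change, 72 h against 1 h in WT and ACX. Requiring 2-fold changes left 1624, 4396, 1628, 4518, 243, 8, 209, 30, 626, 4166 and 3847 (fewer qualify by construction). With 1 probe set per gene (fewer tested) counts were 3183, 6682, 2766, 6634, 825, 3, 261, 18, 621, 6196 and 5706. Without the lower 50% by mean (fewer tested) they were 7989 (WT 72 h), 7881 (ACX 72 h), 396 (genotype at 72 h), 7335 and 6939 (72 h against 1 h). Array weights gave 45 and 1357 for genotype at 1 h and 72 h, and 322 and 2444 for the differences of the change; the cause was not tested. Fitting only the groups compared left 4 (1 h) and 2 (72 h) genotype calls, with fewer samples. With 0 h replicates 1 to 3 only, the 0 h genotype count was 2691 and the 1 h difference 17; with 4 to 6 only they were 4184 and 1122, and the 72 h difference 2914; the cause was not tested. Crosswise, 0 h gave 493 and 924; without ACX 0 h replicates 3 and 6 it gave 1101 and the 1 h difference 70. The arrays showed no regular pairing by replicate number (10 of 48 same-numbered pairs with r over 0.1, range -0.509 to 0.356, 6 of 24 arrays closest to their own number in other groups). Pairing of some arrays is not ruled out, as ACX 0 h and 1 h had r = 0.291, -0.163 and 0.356 for replicates 1, 2 and 3. The replicate block moved the 1 h difference to 18 and no other count by over 1.5 times. It ended 16 calls of genes and 3 of lists; those given in the text were FMA (WT 72 h, adjusted p = 0.0882), HYH and SBPASE (genotype at 72 h, 0.0519 and 0.0606), COR15A and EXPA16 (1 h difference, 0.0877 and 0.0855), SBPASE, SAG29 and AT2G29500 (72 h difference, 0.0683, 0.0595 and 0.0688) and the lists for reactive oxygen (ACX 72 h, 0.0769; 0 h genotype, 0.0539) and detoxification (ACX 72 h, 0.0519). Leaving out an array gave ranges of 4371 to 6349, 10484 to 12306, 3478 to 5746, 10345 to 12603, 1085 to 2263, 4 to 14, 209 to 865, 6 to 138, 705 to 1751, 9785 to 10150 and 8814 to 9915. Centring and quantile normalization kept every total within 1.5 times, but centring raised the lower calls from 6146 to 10521 (WT 72 h), 6135 to 10012 (ACX 72 h), 5557 to 10451 and 5135 to 9218 (72 h against 1 h). Of 2422 values of named genes under other settings 2308 kept their call and 114 lost it. Of 2094 with an array left out 1951 kept it and 143 (36 results) lost it. These genes were called in the main fit and many were chosen for large changes in these data, so a high share kept is expected. Of 348 values of lists 32 lost a call. The other 316 had the same outcome as in the main test, which includes lists called in neither. An estimated correlation alone ended 16 list calls. None of these values reversed. Low signals are compressed by RMA, which limits small changes of weakly expressed genes.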

Other observations

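In this part the overlap of independent lists was tested only after the result was seen; families were written after the annotation was seen and before any comparison.

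Of 8 measured autophagy genes, all 8 rose at 72 h in WT (median 1.97) and in ACX (median 1.56), and centring gave medians of 1.82 and 1.43. Camera placed the family above other genes (adjusted p = 0.000101 in WT and 0.000365 in ACX), but not with an estimated correlation (adjusted p = 0.353 and 0.497). At 1 h 2 of the 8 rose in each genotype. The families below also kept the direction of their medians under both scalings. Of 69 plastid genome genes 36 fell in WT at 72 h and none rose, and 37 fell and 1 rose in ACX (medians -0.46 and -0.58; adjusted p = 0.000818 and 0.000803, and 0.608 and 0.712 with an estimated correlation). Of 47 UDP-glycosyltransferase genes 15 rose and 6 fell in WT at 1 h (adjusted p = 0.00424; 0.169 with an estimated correlation), and 15 rose and 4 fell in ACX (0.00241 and 0.136). Of 13 genes of organelle transcript processing 7 fell in WT at 1 h and 4 in ACX, with none higher (adjusted p = 0.00518 and 0.00616, and 0.169 and 0.136 with an estimated correlation). Of 7 calmodulin-like genes 3 were higher in ACX than in WT at 0 h and 4 did not pass the test (median 0.96). Camera placed the family above other genes (adjusted p = 3.59e-05), but not with an estimated correlation (adjusted p = 0.303).

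Probe sets called between genotypes at both 0 h and 72 h mostly had opposite signs, 74 against 23 with the same sign, where independent lists would give 23.5 and 23.2. Over all probe sets 48% of the differences had the same sign at both times (r = -0.166). The 74 thus exceed what independent lists give. Scaling does not account for them, since the lower of the numbers under centring and quantile normalization was 65. The reference of 23.5 takes probe sets as independent, which they are not, so the excess does not exclude chance. The genotype difference of the 72 h change was called with the opposite sign at 337 of the probe sets higher and 293 of those lower at 0 h (22.7 and 27.4 for independent lists), but it contains the same 0 h arrays, so that the source of the opposite signs stays open.

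As values only, with the WT 0 h arrays divided so that none is shared, the 0 h genotype difference correlated with the WT 1 h change across probe sets at r = 0.206 and 0.244 (0.391 when all WT 0 h arrays enter both). Probe sets are not independent replicates, and these correlations do not bear on the opposite signs at 0 h and 72 h.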
